A study of Rattus norvegicus with 2 samples.

How the data were processed

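The series measured messenger RNA in primary rat hepatocytes, the parenchymal cells of the liver kept in short-term culture, with Affymetrix Rat Genome 230 2.0 GeneChips. Per the labels, the cells came from male Sprague-Dawley (SD) rats, grew on collagen-coated plates in a hepatocyte medium with growth factors, and were either left untreated or given triiodothyronine (T3), the active thyroid hormone, at 1 nM for 24 h. Total RNA was extracted and labelled with biotin by the array maker's standard protocol. There was 1 control array and 1 T3 array, so there are no replicates, no gene's difference between the groups was tested and no p-value is given. Intervals and percentiles describe genes or probe sets within these arrays, not the spread between cultures. The number of arrays limits the precision of every value, and the spread between cultures cannot be estimated from these 2 arrays.

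The authors deposited 1 intensity per probe set and array, which the column names per the file headers call a MAS5 signal after normalization. The submitters' processing notes name Affymetrix Expression Console; its version and the scaling target are not given in the sources used here. Both arrays had a trimmed mean signal of 100.04 with 2% of the probe sets left out at each end, so the intensities had been scaled to a common level by the authors before deposit. The authors also deposited a MAS5 detection p-value and a detection call of present, marginal or absent, which score whether the perfect-match probes of a probe set are brighter than their mismatch partners on that array. Present calls reached a detection p-value of 0.0461, and absent calls began at 0.0676. The deposited ratio column is the T3 intensity over the control intensity, and it equalled the quotient of the signal columns within rounding error of the computer. The deposited sheets of probe sets past 1.5-fold and 2-fold hold the same ratio for part of the probe sets. The authors' series value table holds the same intensities for all 31095 probe sets compared.

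Mean signal is the arithmetic mean of both arrays' signals where a probe set is chosen per gene, where mean signals of a group are stated and at the limit of 100. It is the geometric mean at the limit of 69.4, in bins, in the nearest probe sets, in loess and in the filter on dim probe sets. The log2 ratio was computed here from the deposited signals with no pseudocount, and a positive value means a higher signal with T3. Of 31095 probe sets, 57 array controls were left out and 31038 were analysed. A probe set called present was taken as detected. A probe set was counted as past a threshold when its ratio was at least 1.5 or 2 in either direction and it was detected on the brighter array. Probe sets were named through the gene number in the file with the gene table of rat assembly GRCr8, used for names only. In total 19169 probe sets had 1 symbol, of which 18645 were named by gene number and 524 kept the symbol of the file. A further 599 carried several symbols and 11270 had none, and no gene was named from these. The symbols of 22 probe sets stood in the file as calendar dates, and all 22 were named by gene number. No chromosome positions are given, because the files name no genome build. Each gene is represented by the probe set with the highest mean signal among those detected on at least 1 array, which gave 9671 genes. A gene detected on the brighter array only has a bound: its signal there over the higher of its own signal and the lowest present signal on the other array, written as "at least". This divisor is not a detection limit. On the T3 array absent signals had a median of 4.32, and the 25th percentile of present signals was 39.4. A bound is therefore not a firm lower limit of the fold. Symbols of the cytochrome P450 and UDP-glucuronosyltransferase families are uncertain, since probes of near-identical family members can share transcripts.

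In place of a replicate error, each gene's log2 ratio was ranked among the 500 probe sets nearest to it in mean signal and detected on both arrays. That rank holds biological and technical differences together. Gene lists were described by the median log2 ratio of their detected members, with a 95% bootstrap interval over members, and by the percentile of this median among 10000 random lists of the same size matched in 10 bins of mean signal. The percentile describes these 2 arrays only. With 22 lists set against the central 95% of random lists, some can lie outside it by chance, and no correction for their number was made. The 22 lists, fixed before the data were examined, were thyroid hormone signalling and transport; classical thyroid hormone-induced liver genes; synthesis of fatty acids and triglycerides; cholesterol synthesis and uptake; bile acid synthesis and sterol export; fatty acid oxidation and ketogenesis; oxidative phosphorylation; mitochondrial biogenesis, uncoupling and shuttles; gluconeogenesis, glycolysis and glycogen. The others were the urea cycle with amino acid catabolism; drug-metabolising enzymes; hepatocyte identity; coagulation; the acute phase; the growth hormone axis; the circadian clock; the cell cycle; stress and antioxidant genes; and markers of stellate cells, leukocytes, endothelial cells and bile duct cells.

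Genes to be named were fixed by rule before the data were examined. They were the 12 highest and 12 lowest log2 ratios among genes detected on both arrays with a geometric mean signal of at least 69.4, the 25th percentile of such genes. They also included the 4 brightest genes detected on 1 array only and past 2-fold in each direction. From each list up to 3 members past 1.5-fold per direction were added, or the 2 brightest where none was. Thrsp, Me1, Dio1, Thrb, Klf9, Hr, Cyp7a1, Pck1, Fasn, Cpt1a, Igf1 and Alb were named in any case. Other genes named in the text were chosen after their values were seen. Genes with several detected probe sets gave the only repeat measurement, which is technical, and shares of agreement carry exact Clopper-Pearson 95% intervals.

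Alternatives covered pseudocounts of 16 and 64, the detection filter, a filter on dim probe sets, median centring, quantile normalization, loess of the log2 ratio on mean signal with a span of 0.3, the choice of probe set per gene and the series value table. The list step was tested on simulated data for the comparison of T3 with control over 9671 genes. Of 200 random lists, 4.5% lay outside the central 95% of random lists, and 99% of simulated lists of 22 genes shifted by 0.2 on the log2 scale lay above that range. All of these lists held genes drawn at random from shuffled ratios. The step thus checks the computation and cannot show how often lists of co-regulated genes leave that range. Over 16524 simulated probe sets, 98% of 50 planted 2-fold differences and 100% of 50 planted 3-fold differences came out past 1.5-fold. Only probe sets present on both arrays were simulated. These shares do not apply to probe sets present on 1 array, which were 171 of the 234 higher and 133 of the 161 lower at 2-fold. Probe sets with no values in the deposited ratio table were not used here, and the individual values of some list members and annotation terms are not reported here. The computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.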

Results

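RNA of primary rat hepatocytes cultured with or without T3 was measured on 1 array per group, to find thyroid hormone-responsive genes in these cells. On the control array 17592 of 31038 probe sets (56.7%) were called present, and on the T3 array 17264 (55.6%). Both arrays called 16524 probe sets present, 18332 were present on at least 1 array and 12706 on neither. The log2 signals of the probe sets present on both arrays correlated across probe sets with Pearson's r = 0.990; probe sets are not independent replicates. Their median log2 ratio was -0.01.

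Among genes detected on both arrays with a geometric mean signal of at least 69.4, Pck1 had the highest ratio of T3 to control signal. Pck1 encodes cytosolic phosphoenolpyruvate carboxykinase, a control step of gluconeogenesis, and its signal was 44.5 in control and 162 with T3, a ratio of 3.65. The terminal complement component C9 was 2.48-fold higher (60.2 and 150) and Septin4, a GTP-binding cytoskeletal protein, 2.33-fold higher (131 and 306). Klf9, a zinc-finger transcription factor known as a direct thyroid hormone target, was 1.86-fold higher, with signals of 309 and 575. The other genes among the 12 highest were Gmeb2 at 1.81-fold, the aldehyde dehydrogenase Aldh1a7 at 1.77-fold, the ubiquitin ligase scaffold Cul4a at 1.71-fold and the secreted serine protease Htra1 at 1.71-fold, with Htra1 signals of 457 and 781. Plekhj1 was 1.71-fold, the glycolipid transfer protein gene Gltp 1.66-fold and the mitotic kinase gene Aurka 1.63-fold higher. Ints13, a subunit of the Integrator complex, was 1.70-fold higher in its brightest probe set, while its other detected probe sets gave 2.49 and 0.750. These 12 genes ranked between percentiles 99.4 and 99.8 of probe sets of like signal, as genes chosen for a high ratio must.

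At the other end of the same genes, Anp32a, which encodes an acidic nuclear phosphoprotein, had a T3 signal of 284 against 637 in control, 0.445 times the control level. Chtf8, a subunit of an alternative clamp loader, stood at 0.533 times control (202 and 108), and its other detected probe set, absent with T3, at no more than 0.335. The early-endosome GTPase gene Rab5c stood at 0.551, the focal adhesion gene Lims1 at 0.562, Kptn at 0.580 and Mef2a at 0.582 times control. For Mef2a the title in the file is that of a Mef2c-like sequence, and a second detected probe set gave 1.07. Dnal1 was at 0.589 with a second probe set at 0.778, and Pik3cd at 0.633 with a second one at 1.03. Opa1, the GTPase that fuses the inner mitochondrial membrane, was at 0.611, the transglutaminase gene Tgm1 at 0.627 with signals of 601 and 377, Dhrs9 at 0.650 and the annexin gene Anxa8 at 0.658. There is no replicate check on any of these differences.

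**Figure D1:**
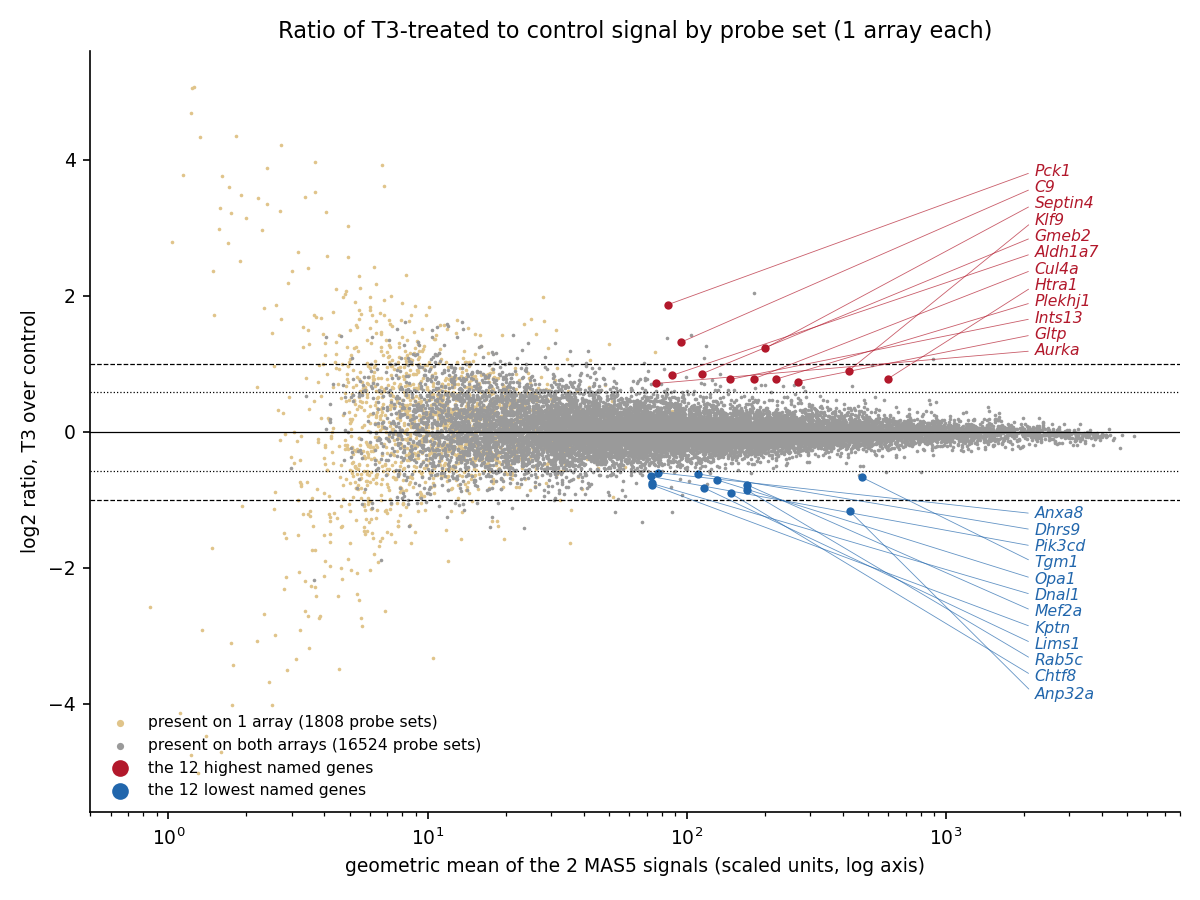
Log2 ratio of T3 over control signal (y axis) against the geometric mean of both MAS5 signals (x axis, log scale) for each probe set present on at least 1 array; dashed and dotted lines mark 2-fold and 1.5-fold. The 12 highest named genes reach 3.65-fold in Pck1 and the 12 lowest 0.445 times control in Anp32a, while probe sets present on 1 array only lie mostly at low signal and spread widely.

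Over all probe sets, 234 were at least 2-fold higher and 161 at least 2-fold lower with T3. These included Igfbp4, Mlxipl and Ugt2b among the higher and Anp32a and Galnt10 among the lower. Present on both arrays were 63 of the higher and 28 of the lower. At 1.5-fold, 754 were higher and 485 lower, so that 60.9% of those past the threshold were higher; after quantile normalization the counts were 605 and 609, with 49.8% higher. Most of these probe sets were dim: the median of their mean signals was 9.00 for the 234 and 6.61 for the 161, and only 9 of the 234 and 1 of the 161, that of Anp32a, had an arithmetic mean signal of at least 100. By the geometric mean these were 6 and 1. The 234 included 110 genes with 1 symbol and the 161 included 81.

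The ratio spread more at low signal. With the probe sets present on both arrays in 5 bins of equal size, in the dimmest bin (geometric mean signals of 2.98 to 35.7) the central 95% of ratios ran from 0.606 to 1.86, and in the brightest bin (313 to 5310) from 0.854 to 1.19. Of probe sets present on both arrays 96.1% lay within 1.5-fold. A ratio past 2-fold was found in 0.551% of them and in 39.0% of probe sets present on neither array. The 18 hybridisation control probe sets, for spiked-in bacterial transcripts, had ratios of 0.930 to 1.21. The 24 poly-A control probe sets, meant for transcripts added before labelling, had ratios of 0.756 to 1.26 at signals of 9.57 to 254; the sources used here do not say whether these were added. The ratio of 3' to 5' signal, a measure of RNA integrity, was 1.32 in control and 1.38 with T3 for beta-actin and 1.15 and 1.16 for Gapdh.

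Different probe sets of a gene often disagreed. Among genes with a pair of detected probe sets, both went the same way in 57.0% (1077 of 1888 genes, 54.8 to 59.3), where chance gives 50%. Where 1 of the pair was past 1.5-fold, the share was 49.7% (75 of 151 genes, 41.4 to 57.9). In 5 of 2481 genes with at least 2 detected probe sets, all of these were past 1.5-fold in the same direction. Bcan (at least 2.72-fold and 5.35-fold) and Mrm1 (1.88-fold and at least 2.69-fold) were higher. Cars2 (at most 0.620 and 0.629 times control), Chtf8 and Kazn (0.618 and at most 0.441 times control) were lower. Apart from Chtf8, their probe sets had mean signals of 27.3 or less. Of all probe sets present on at least 1 array, 4.11% were past 1.5-fold higher and 2.65% past it lower. Unrelated probe sets would therefore also give some genes with all probe sets past 1.5-fold in the same direction. Their number was not computed, so these 5 genes are not singled out by a repeat measurement.

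Some genes were detected in 1 condition only. Igfbp4, which encodes a secreted binding protein of insulin-like growth factors, was absent in control and present with T3 at a signal of 78.6, at least 2.44-fold higher. Lsm11, a component of the histone mRNA processing particle, was at least 3.16-fold higher, the microtubule-associated protein gene Map1a at least 2.10-fold and Zfr2 at least 2.08-fold. A second Zfr2 probe set, present on both arrays, was 1.38-fold higher. In the other direction, Galnt10, a glycosyltransferase that starts mucin-type O-linked chains, was at least 10.04-fold lower with T3. Its control signal was 33.4 and its absent T3 signal 3.33, so the size of that fold is uncertain. The apoptosis regulator gene Bcl2a1 was at least 2.62-fold, Rpap1 at least 2.49-fold and C14h5orf52 at least 3.72-fold lower.

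Thyroid hormone-responsive genes fixed in advance differed among themselves. Thrsp (Spot 14), a lipogenic gene known for its response to thyroid hormone, had signals of 34.2 and 51.2, a log2 ratio of 0.58, and its other probe sets were 1.35-fold higher and, in the one absent in control, at least 1.48-fold higher. Cpt1a, which controls fatty acid entry into mitochondria, was 1.41-fold and 1.29-fold higher in its probe sets. Me1, the cytosolic malic enzyme, was near equal at 0.997 and 1.10, as were Fasn (1.10 and 1.03) and Igf1 (1.10). The albumin gene Alb was at 0.868 and 0.876 times control. Dio1, the type I deiodinase, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, were absent on both arrays, and Hr was marginal in control and absent with T3, so none of these has a ratio here. The thyroid hormone receptor gene Thrb was barely detected, with signals between 8.30 and 12.4.

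**Figure D2:**
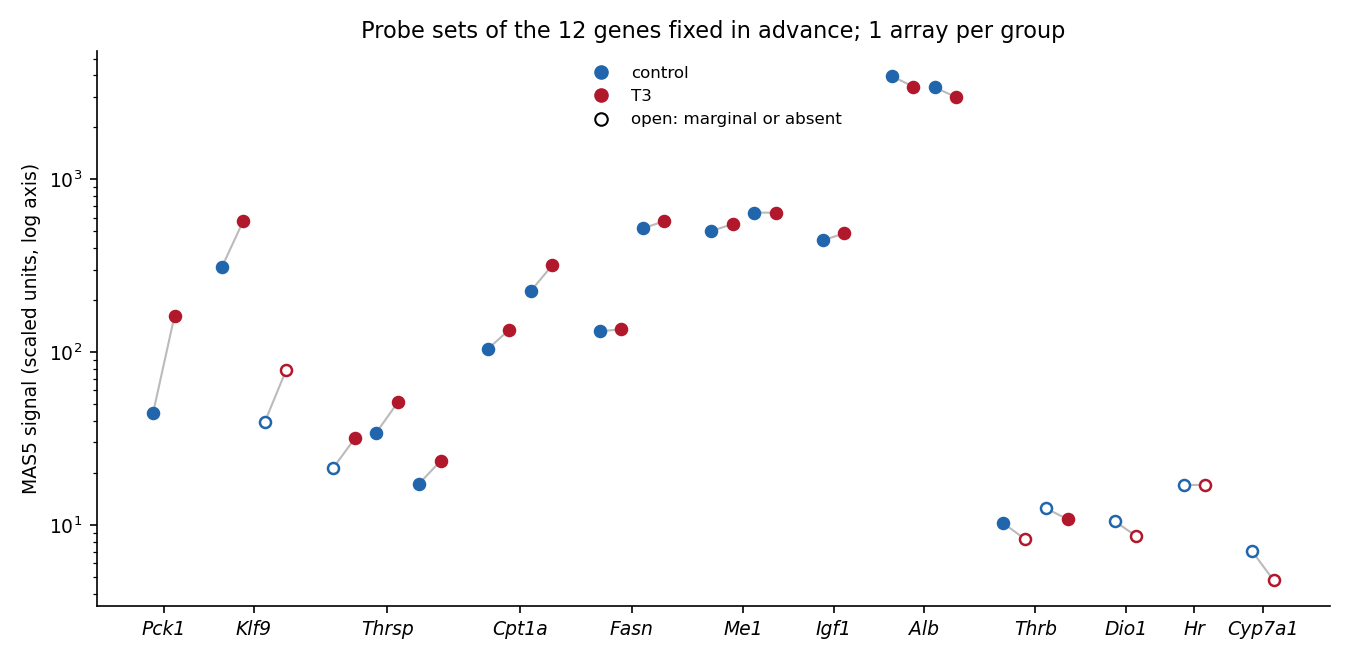
MAS5 signal (y axis, log scale) in control (blue) and with T3 (red) for each probe set of the 12 genes fixed in advance (x axis), 1 array per group, with open circles for marginal or absent calls. Pck1, Klf9, Thrsp and Cpt1a are higher with T3 in each of their probe sets present on both arrays, whereas Dio1, Hr and Cyp7a1 are not detected.

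As a group, the classical thyroid hormone-induced liver genes were higher with T3. Of 22 detected members 4 were past 1.5-fold and higher, 0 were lower, and 15 lay above 0. Besides Pck1 and Klf9, these were the glucose-responsive transcription factor gene Mlxipl (ChREBP), at 2.01-fold, and the glucose-6-phosphatase gene G6pc1, at 1.64-fold. The median log2 ratio was 0.20 (0.02 to 0.50), at percentile 100 of random lists. Bcl3 (1.37-fold) and Por, the electron donor of microsomal cytochromes P450 (1.47-fold), were also above. A dimmer probe set of Por had a log2 ratio of -0.02, and 19 of the 22 members also stand in another list. The receptors, coregulators, deiodinases and transporters of thyroid hormone showed no such shift: 0 of 16 were past 1.5-fold, with a median of 0.01 at percentile 58.4. Ttr (2232 and 2273) and Sult1a1 (1073 and 1115) were the brightest of them.

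The medians of the 4 lipid lists fixed in advance lay inside the central 95% of random lists. In fatty acid and triglyceride synthesis, 1 of 30 members was past 1.5-fold and higher, Mlxipl, and 1 lower, the acetyl-CoA carboxylase gene Acacb, which was at least 1.63-fold lower and absent with T3; the median was 0.01, at percentile 75.8. In cholesterol synthesis and uptake 0 of 29 were past 1.5-fold, with Fdps at 1.01 and Msmo1 at 0.992 times control and a median of -0.01 at percentile 47.5. Among 16 genes of bile acid synthesis and sterol export 2 were higher, the bile acid-CoA ligase gene Slc27a5, at least 1.97-fold, and the steroid reductase gene Akr1d1, at 1.66-fold, both with signals under 15; 0 were lower and the median was 0.10, at percentile 88.6. Fatty acid oxidation and ketogenesis had 0 of 35 past 1.5-fold and a median of 0.00, at percentile 61.9, with Acadl at 0.941 and Hadhb at 1.03 times control. Within it Echs1, an enzyme of mitochondrial beta-oxidation, was 1.42-fold higher.

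Oxidative phosphorylation genes stood slightly higher, and genes of glucose metabolism did so when each was represented by its brightest probe set. For gluconeogenesis, glycolysis and glycogen the median of 34 members was 0.06 (0.01 to 0.15), at percentile 99.3. Pck1 and G6pc1, which also stand in the classical thyroid hormone-induced list, were past 1.5-fold and higher, and 0 were lower. With the median over each gene's probe sets the list median was 0.04, at percentile 96.1. With the probe set of largest change the list median was 0.05, at percentile 96.5. Both lay inside the central 95% of random lists. Oxidative phosphorylation had 41 of 56 members above 0 and 0 past 1.5-fold, with a median of 0.04 (0.02 to 0.07) at percentile 99.99. Its brightest members were near equal, Cycs at 1.01 and Cox4i1 at 0.977 times control; complex I genes ran from 1.19-fold in Ndufs7 to 0.755 times control in Ndufa5. Mitochondrial biogenesis and shuttles had a median of 0.01, at percentile 73.6, and Opa1 as the 1 member of 25 past 1.5-fold. Of 28 genes of the urea cycle and amino acid catabolism 1 was lower, the histidine-degrading Hal at 0.590 times control (82.8 and 48.8), and 0 were higher, with a median of 0.00 at percentile 60.4.

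Among 25 detected drug-metabolising genes 4 were past 1.5-fold and higher and 1 was lower. The glucuronosyltransferase genes Ugt2b and Ugt2b1 were 2.68-fold and 2.21-fold and Cyp2e1 1.52-fold higher, and Cyp2c22 had a log2 ratio of 0.59. Cyp3a18 was at least 3.73-fold lower, from a control signal of 6.37. The list median was -0.02, at percentile 32.0, and family members with near-identical sequence are not separable here. Hepatocyte identity genes had a median of 0.01 at percentile 81.7. Of their 37 members 1 was higher, the corticosteroid-binding globulin gene Serpina6, at least 2.19-fold, and 1 lower, the hepatic transcription factor gene Prox1, at least 1.79-fold; both signals were under 15.

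Acute phase and inflammation genes had 2 of 28 members past 1.5-fold, C9 and the interferon-induced chemokine gene Cxcl10 at 1.62-fold, 0 lower, and a median of 0.04 at percentile 95.1. The haptoglobin gene Hp was 1.42-fold higher, with signals of 447 and 634. Coagulation and fibrinolysis had 0 of 18 past 1.5-fold and a median of -0.05, at percentile 7.16, with Plat at 0.968 and Fgg at 1.04 times control. In the growth hormone axis Igfbp4 was the 1 higher member of 19. The growth hormone receptor gene Ghr was the 1 lower, at 0.645 times control, although a second Ghr probe set gave 1.01; the median was 0.10, at percentile 95.8.

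Stress and antioxidant genes stood lower as a group. Of 38 members 26 lay below 0, the median was -0.06 (-0.11 to -0.01), at percentile 0.590; with the probe set of largest change per gene the percentile was 2.92, inside the central 95% of random lists. Past 1.5-fold was 1 member, Srxn1, which encodes the peroxiredoxin-repairing sulfiredoxin, at 0.659 times control (725 and 478), with a second probe set at 0.812. The cystine transporter gene Slc7a11 (137 and 102) and the heat shock gene Hspb1 (1291 and 1059) lay on the same side. Cell cycle genes had Aurka as the 1 member of 43 past 1.5-fold, 30 above 0 and a median of 0.04 at percentile 96.4. Of 14 clock genes 1 was higher, Per3, at least 2.23-fold and with a signal of 12.7 with T3, and 0 were lower; the median was -0.08, at percentile 7.53.

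Transcripts on the marker lists of other liver cell types were detected in both cultures. Stellate cell and fibroblast markers had 19 of 30 members detected, a median of -0.08 at percentile 3.13, and 2 lower members, both dim: Col6a3, at least 3.20-fold, and Lrat, at 0.532 times control. The bright Vim (1621 and 1418) and Tagln (1096 and 986) were below control too, among 12 members below 0. The other 7 lay above 0, including Acta2 (102 and 124) and Des (46.4 and 56.6). Bile duct markers had 14 of 19 detected, 0 past 1.5-fold and a median of -0.04 at percentile 17.7. They included Krt19 (1240 and 1079) and Epcam (1038 and 901), while Anxa2 and Anxa3 were at 0.948 and 0.986 times control. Of 28 leukocyte markers 25 have a named probe set and 4 were detected, with Cd163 1.60-fold higher at signals of 4.79 and 7.64 and a median of 0.25 at percentile 85.0. Of 22 endothelial markers 18 have a named probe set and 6 were detected, with Egfl7 1.54-fold higher, Ramp2 at 0.581 times control and a median of -0.11 at percentile 14.4.

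**Figure D3:**
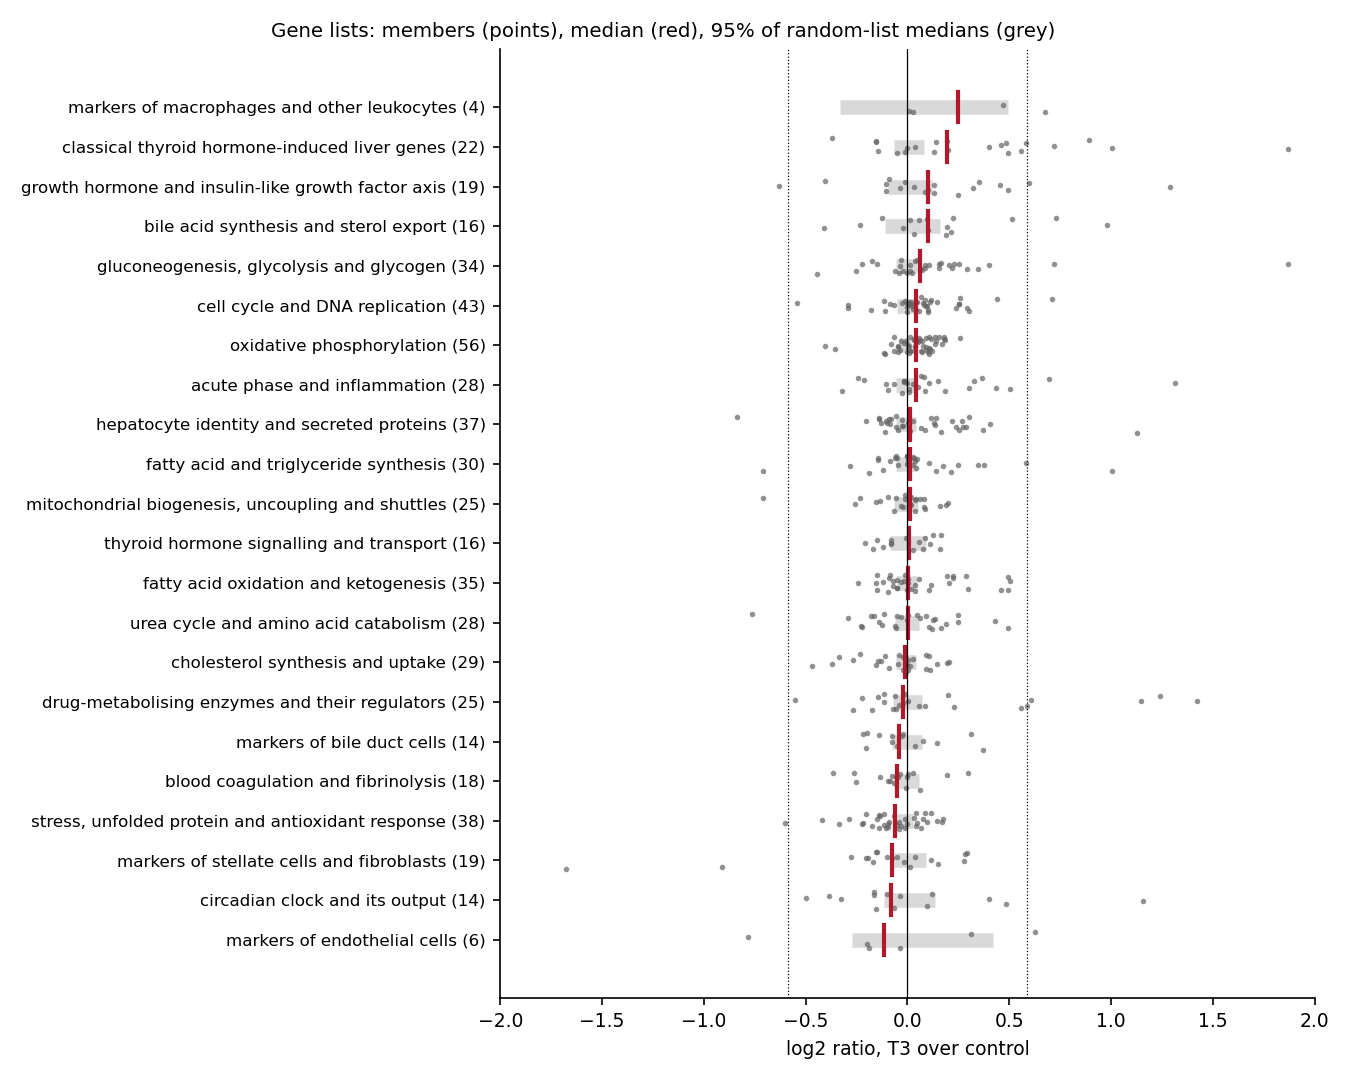
Log2 ratio of T3 over control (x axis) for the detected members of each gene list (rows, number of members in brackets), with list medians as red bars and the central 95% of medians of matched random lists as grey bars; dotted lines mark 1.5-fold, and 1 member, Cyp3a18, lies outside the axis. The classical thyroid hormone-induced genes (median 0.20), gluconeogenesis, glycolysis and glycogen (0.06) and oxidative phosphorylation (0.04) lie right of their grey bars, and the stress and antioxidant genes (-0.06) left of theirs.

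The authors' deposited tables of selected probe sets held 234 and 754 probe sets higher and 161 and 487 lower, at 2-fold and 1.5-fold. A rule of the ratio plus a present call on the brighter array gave all of the probe sets in the authors' deposited tables except 2. Both of these were in the authors' deposited table of 1.5-fold lower probe sets, at a ratio of 0.667.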

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

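Every alternative was chosen before the data were examined, except the geometric in place of the arithmetic mean signal, chosen after seeing the data. The counts past a threshold depended on how dim probe sets were treated. Higher and lower at 2-fold were 14 and 4 with a pseudocount of 16, 2 and 1 with a pseudocount of 64, 2977 and 2382 without a detection filter, 63 and 28 with detection required on both arrays, and 6 and 1 with a mean signal at or above the median. At 1.5-fold the same settings gave 119 and 62, 17 and 7, 4867 and 3668, 426 and 224, and 33 and 15. These differences follow from how the settings treat dim probe sets, since pseudocounts shrink their ratios and filters remove or admit them. Median centring, loess, quantile normalization and the series value table kept every count within 1.5 times; loess gave 198 and 185 at 2-fold and 641 and 569 at 1.5-fold. All 154 alternative list medians stayed inside the bootstrap interval of their list. The classical thyroid hormone-induced list ranged from percentile 99.98 to 100, oxidative phosphorylation from 99.86 to 100, gluconeogenesis from 96.1 to 99.6, and stress and antioxidant genes from 0.0900 to 2.92; the last 2 thus entered the central 95% of random lists under another choice of probe set, and the cause was not tested. In the other direction, 3 lists inside that range left it under some alternatives: acute phase and inflammation (87.7 to 99.6), the growth hormone axis (70.0 to 98.7) and, without a detection filter, the stellate cell markers (0.480 to 33.6). The thyroid hormone signalling list ranged from 8.27 to 81.2. For named genes 473 alternative log2 ratios moved by less than the spread of probe sets of like signal and 11 by more, all but 1 of these by taking the median over a gene's probe sets, and none past 1.5-fold turned its direction. The alternative of a change call could not be run, since the tables used here hold no such call. No paired analysis was possible because each group has 1 array. Signal over background limits these data: below a geometric mean signal of about 35.7 a ratio of 1.5 lies within the central 95% of all ratios.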

Other observations

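Of the tests below, that of the thyroid hormone-induced list without its members past 1.5-fold was fixed before its result was seen; those of probe set agreement, hepatocyte identity, scaling, a signal-dependent trend and ribosomal protein genes, and the survey of annotation terms, were chosen afterwards.

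Among the annotation terms in the file, lipid transport and triacylglycerol metabolism were among the highest and cell shape among the lowest. Of 337 biological process terms with 10 to 200 detected genes, 3 lay in the top 0.5% of random lists and 9 in the bottom 0.5%, where chance gives 1.69 on each side. Triacylglycerol metabolic process was the highest, with a median log2 ratio of 0.23 over 10 genes and 8 of them above 0. It held the apolipoprotein genes Apoc3 (log2 ratio 0.27, signals of 1065 and 1282), Apoc2 (1.23-fold) and Apoa5 (1.22-fold) and the hepatic lipase gene Lipc (1.18-fold, 1432 and 1688). Lipid transport (24 genes, median 0.08) and organ regeneration (11 genes, median 0.19) were the others. Lipid transport also held Apoc2, Apoa5 and Apoc3, so it and triacylglycerol metabolic process are not separate observations. At the low end, regulation of cell shape had a median of -0.16 with 15 of 18 genes below 0. Cell adhesion had a median of -0.05 over 137 genes. Cholesterol biosynthetic process had a median of -0.10 with 13 of 18 genes below 0, at percentile 0.0900; Lss (176 and 127) and Idi1 (1002 and 792) were among them. The fixed list of cholesterol synthesis and uptake did not stand apart (percentile 47.5), so that shift depends on which genes make up the list.

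Of 9 probe sets at least 2-fold higher with an arithmetic mean signal of at least 100, 3 have no gene symbol. They include the highest of the 9, with signals of 89.7 and 367 (4.09-fold), and one with signals of 617 and 1295 (2.10-fold). Another of the 9, of Trappc5, was 2.11-fold higher, while the brightest probe set of that gene was at 0.959 times control.

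Most probe sets past 1.5-fold had a mean signal under 100, and measurement noise near background is a candidate explanation for them. Where the gene had another detected probe set, each was compared with the median log2 ratio of the gene's other detected probe sets. This median had the same sign in 50.7% of cases (113 of 223, exact 95% interval 43.9 to 57.4), as noise would give. A gene with several probe sets past 1.5-fold counts several times, which the interval does not allow for. For probe sets with a mean signal of at least 100 the share was 60.0% (9 of 15, 32.3 to 83.7), too few to decide. Split at a geometric mean of 100, the shares were 51.1% (115 of 225) and 53.8% (7 of 13). Probe sets of a gene can also measure different transcript ends, which was not tested.

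The classical thyroid hormone-induced genes lay above random lists, and a response to T3 is the hypothesis the design offers. Scaling between the arrays as the whole cause is argued against by the list median, which was 0.20 before correction, 0.20 after quantile normalization (bootstrap interval 0.02 to 0.50) and 0.20 after loess (0.02 to 0.51). Nor do the 4 members past 1.5-fold carry it alone, since the other 18 had a median of 0.14 at percentile 99.89. More or better preserved hepatocytes in the T3 culture may contribute and stay open: the list exceeded the hepatocyte identity genes by 0.18 in median log2 ratio, with a bootstrap interval from -0.02 to 0.52. With 1 culture per group, a difference between cultures unrelated to T3 was not tested.

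Oxidative phosphorylation genes lay above random lists by a small shift. The signal-dependent trend between the arrays ran the other way at high signal, where the median log2 ratio of the brightest bin was -0.01. Removing the trend by loess raised the list median from 0.0432 to 0.0549 (0.03 to 0.09). That rise follows from the direction of the trend. The random lists were already matched on mean signal, so loess adds no separate evidence. A technical gain of short, abundant transcripts would raise ribosomal protein genes as well. These 67 genes had a median of -0.05, and the oxidative phosphorylation median exceeded theirs by 0.0927 (0.07 to 0.12); after quantile normalization, which took the ribosomal genes from percentile 0.570 to 33.9 of random lists, the excess was 0.05 (0.03 to 0.09). A coordinated response of respiratory chain genes to T3 stays a hypothesis, and a difference between the cultures was not tested.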
